A study of Caenorhabditis elegans with 4 samples.

How the data were processed

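Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole hermaphrodite Caenorhabditis elegans at the third larval stage (L3), grown at 20 degrees Celsius. The strain carries a transgene in which GEI-11 is fused to GFP, together with a wild-type copy of unc-119, in an unc-119 mutant background. Per the labels' protocols, worms were crosslinked with formaldehyde and sonicated, part of the lysate was kept as input DNA, and the rest was precipitated with goat antibodies against GFP. There were 4 samples: 2 of input DNA and 2 of anti-GFP ChIP, numbered replicate 1 and 2 in each group. The labels do not say whether the replicates came from separate worm cultures, so the spread between them may be technical only.

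The authors' sample sheet gives the read counts of each library, which were deposited as total reads of 36 bases. ChIP replicate 1 had 3773496 reads and ChIP replicate 2 had 3560372. Input replicate 1 had 8331974 reads and input replicate 2 had 7222788. The sheet gives uniquely mapped reads as 2500000 and 2800000 for the ChIP libraries and 6000000 for each input library, which look rounded.

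The authors deposited 3 lists of called regions, 1 for each ChIP replicate and 1 for both replicates together. Regions were called with PeakSeq, per the file headers and source column, and each carries a q-value as deposited by the authors. Per the sample sheet the authors deposited, the combined list was called on merged ChIP alignments, the replicate lists came from a replicate verification step on 1 ChIP library each, and a combined input signal belonged to all 3 lists. Every q-value was above 0 and below 0.01. The aligner, the PeakSeq version and its settings are not given in the sources used here. The file headers name the WormBase WS220 genome, while the sample sheet names WS190. Comment lines in the lists record that coordinates were moved to a new build after calling and that the shape of 4 combined regions changed in that step. Coordinates below are those of the lists, in WS220, counted from 1.

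The 3 lists were read without further filtering. The strength of a region is given as −log10 of its deposited q-value. It ranks regions within a list and depends on depth, so its size is not compared as a binding level between lists. The signal along the genome and the reads behind each region were not analysed here, so single regions carry no error. Confidence intervals of shares are exact Clopper-Pearson 95% intervals, and those of densities are exact Poisson 95% intervals. Both cover counting error only and treat regions as independent, which neighbouring regions are not, and PCR reads without molecular identifiers are not independent molecules.

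Regions of different lists were shared if they overlapped by at least 1 bp. Overlap between the replicate lists was compared with 1000 circular shifts of the replicate 2 list within each chromosome, one-sided, with a smallest possible p of 0.001. Strengths were compared across regions that were each other's largest overlap, with Spearman's rho and a two-sided permutation test of 100000 resamples. The combined list was split by whether both replicate lists overlapped a region, and median strengths were compared by a two-sided permutation test of 100000 resamples. The number of combined regions on each chromosome was compared with the chromosome's share of length by a two-sided exact binomial test, with Benjamini-Hochberg adjustment over 6 chromosomes. Chromosome length was taken as the position of the last called region in any list. The share of chromosome IV regions in a pair of piRNA intervals was compared with 1000 circular shifts of that chromosome's regions, two-sided, with a smallest possible p of 0.002 and adjustment over 3 tests. The intervals were 4.5 to 7 Mb and 14 to 17 Mb, approximate positions of the broad piRNA gene domains. The right interval is shorter than the 13.5 to 17.2 Mb usually given for that domain, which was run as an alternative. A region belonged to an interval if its midpoint did.

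The named regions are the 20 combined regions with the smallest q-values that both replicate lists overlap. This rule, the intervals, the tests and most alternatives were set before the data were examined. Planned tests on noncoding RNA genes, gene parts, protein-coding gene sets and a sequence motif needed an annotation or genome of the build of the lists. The gene table at hand is of assembly WBcel235, so these tests were not run and no region is assigned to a gene here. Alternatives covered the overlap rule, the authors' q threshold, the use of each replicate list alone, the merging of regions within 1000 bp, the width of the intervals, full WS220 chromosome lengths and the removal of regions under 50 bp.

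The tests were run on simulated data first. With 2617 simulated regions of which 80% were copied from the other list, the overlap test recovered 80.6%, and with 0% copied it gave 3.33% and a one-sided permutation p of 0.71. With 1856 simulated regions on chromosome IV, 30% of them placed in the right interval, the interval test gave a permutation p of 0.006. The other simulated regions were spread evenly, and the intervals held 51.7% against 31.8% after shifts. This excess was larger than the one in the data, so power to detect a smaller or less even concentration was not shown. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.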

Results

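The series maps where GEI-11 binds the genome of L3 worms. GEI-11, also known as SNPC-4, is a subunit of the complex that activates transcription of small nuclear RNA genes, and it is needed in worms for transcription of piRNAs, the small RNAs that silence foreign sequences in the germline. The data are lists of genomic regions enriched in anti-GFP ChIP over input DNA. The ChIP libraries held 3773496 reads in replicate 1 and 3560372 in replicate 2, against 8331974 and 7222788 in the input libraries.

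Regions were called on all 6 nuclear chromosomes. The combined list held 6192 regions, which covered 2.54 Mb, or 2.54% of the genome. Their median width was 340 bp, with an interquartile range of 236 to 484 bp, and the widest spanned 5981 bp. The narrowest spanned 1 bp, and 341 combined regions, or 5.51%, were under 50 bp wide. Of these, 161 lay in the piRNA intervals of chromosome IV and 77 elsewhere on that chromosome. Replicate 1 alone gave 4368 regions and replicate 2 gave 2617. Replicate 1 thus had 1.67 times as many regions as replicate 2 with 1.06 times as many reads, and fewer uniquely mapped reads by the rounded numbers of the sample sheet. The strength of a region is given below as −log10 of the q-value in the authors' list.

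The strongest regions lay on several chromosomes and were found in both replicates. The strongest combined region was on chromosome II from 13833997 to 13835236, with a −log10 q of 288 in the combined list, 220 in replicate 1 and 212 in replicate 2. The next was a broad region on chromosome IV from 9510432 to 9514460. Its −log10 q was 285 in the combined list, and it spanned 4029 bp there and 3896 bp in replicate 1. In replicate 2 the strongest region at this place was 1167 bp wide, from 9511080 to 9512246. A region on chromosome II from 14803997 to 14805251 reached a −log10 q of 277. A region on chromosome III from 10989193 to 10990147 followed with 202, and one on chromosome II from 5844392 to 5845264 with 201.

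Among the 20 strongest combined regions found in both replicates, 6 lay on chromosome III, 5 on chromosome II, 4 on chromosome I, 3 on chromosome IV, 1 on chromosome V and 1 on chromosome X. They were wider than most regions, between 866 and 4029 bp, with a median of 1207 bp. Their −log10 q ran from 147 to 288 in the combined list. The region on chromosome X spanned 14476486 to 14477751 and had a −log10 q of 184. The region on chromosome V spanned 8500034 to 8500899 and had a −log10 q of 148. The other chromosome IV regions of this set lay at 9444082 to 9445063 and 8428233 to 8429431. None of the 20 lay in the piRNA intervals of chromosome IV, although 85 of the 620 strongest combined regions, or 13.7%, did. The strongest region of each replicate list, on chromosome II from 5543219 to 5544605 in replicate 1 and from 5543178 to 5544535 in replicate 2, overlapped no combined region analysed here and so is not among the 20, and numbers and ranks of combined regions hold for the list as analysed here. Its −log10 q was 265 in replicate 1 and 234 in replicate 2.

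The first comparison asks how far the replicates found the same regions. Of the 2617 regions of replicate 2, 2211 overlapped a region of replicate 1, which is 84.5% (95% exact interval 83.0 to 85.9%). After circular shifts the overlap averaged 3.81% and never passed 5.08% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). In the other direction 2230 of the 4368 regions of replicate 1, or 51.1%, overlapped a region of replicate 2. With the 2617 strongest regions of each list, 71.0% of the replicate 2 regions were shared. Strength rose together in the lists: across 2197 matched regions Spearman's rho was 0.74 (permutation p = 1e-05, the smallest that 100000 resamples can give). This rho is across regions, which are not independent replicates, and the sample sheet names the same combined input signal for both lists, so separate controls cannot be assumed.

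**Figure D1:**
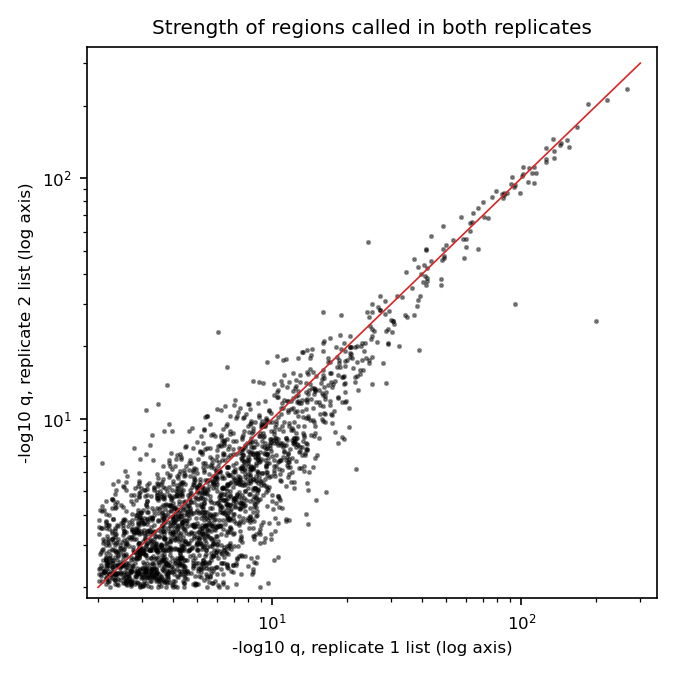
Strength of the 2197 regions matched between the replicate lists, as −log10 q in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), 1 point per region, with the line of equality in red. Spearman's rho across regions was 0.74, and the points spread most at low strength. Matching was by largest overlap, so the chromosome IV region starting at 9510492 is plotted at 200 against 25.6. A replicate 2 region with a −log10 q of 148 also overlapped it.

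The combined list was much longer than the part that both replicates found. Of its 6192 regions, 2179 (35.2%, 95% exact interval 34.0 to 36.4%) overlapped regions of both replicates. A further 1738 (28.1%) overlapped replicate 1 only, 377 (6.09%) overlapped replicate 2 only, and 1898 (30.7%) overlapped neither. Regions found in both replicates were stronger, with a median −log10 q of 9.94 (interquartile range 7.01 to 16.3) against 3.1 (2.45 to 4.06) for the 4013 others. The difference of medians was 6.84 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). They were also wider, with a median of 457 bp against 287 bp. The combined q-values were computed from the same reads as the replicate lists, so strength and replicate support are not independent measures.

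Replicate support fell steeply along the ranking, which was split into 10 rank classes of equal size. All 620 regions of class 1, the strongest, were found in both replicates, as were 97.6% of class 2 and 82.6% of class 3. The share was 48.8% in class 4 and 19.1% in class 5. In classes 7 to 10, only 1 region of class 8 was found in both. The share of regions on chromosome IV stayed between 24.1% and 34.9% in all 10 classes.

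**Figure D2:**
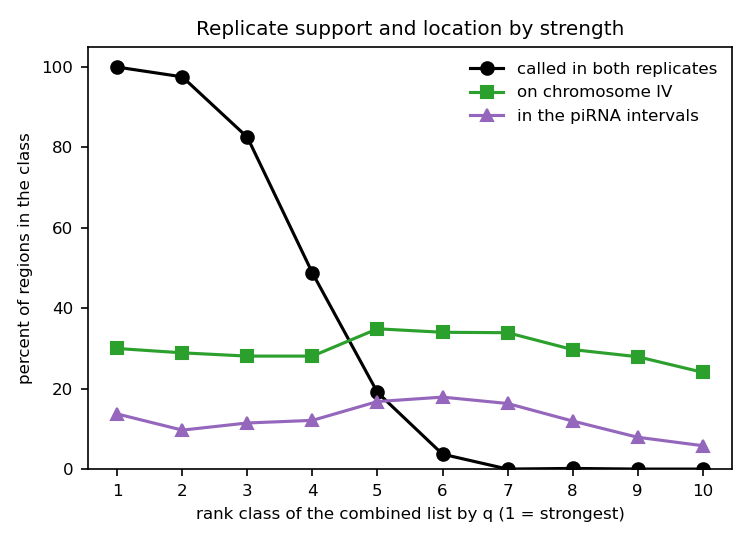
Share of combined regions (y axis, percent) found in both replicates, on chromosome IV, and in the piRNA intervals, in each of 10 rank classes of the combined list by q (x axis, class 1 is strongest). Support in both replicates falls from 100% to 0%, while the chromosome IV share stays between 24.1% and 34.9%.

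The second comparison asks how regions were distributed over the chromosomes. Chromosome IV, which carries most of the piRNA genes of the worm, held 1856 of the 6192 combined regions, or 29.97% (95% exact interval 28.8 to 31.1%), against 17.5% of the length. This was 1.72 times its share of length (exact binomial test, adjusted p = 1.7e-127). Chromosome III was 1.09 times its share of length, with 929 regions (exact binomial test, adjusted p = 0.0057), but did not pass among the 3096 best scored regions, at 1.08 times (exact binomial test, adjusted p = 0.091). Chromosomes I, V and X held fewer regions than their length gave, at 0.78, 0.72 and 0.76 times their share (exact binomial tests, adjusted p = 3.5e-14, 2e-31 and 2e-19). Chromosome II, at 0.98 times its share, did not pass the test (exact binomial test, adjusted p = 0.51), but was above its share among the 2179 regions found in both replicates, at 1.12 times (exact binomial test, adjusted p = 0.023). The binomial test treats regions as independent, so these p-values are too small to the extent that regions cluster.

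The chromosome IV share was 30.3% in the replicate 1 list and 28.9% in the replicate 2 list. It was 26.9% among the 2179 combined regions that both replicates overlapped. The density on chromosome IV was 106 regions per Mb, against 52.5 per Mb over the other chromosomes together. Chromosome III had 67.5 regions per Mb, chromosome II had 60.6, chromosome I had 48.0, chromosome X had 46.9 and chromosome V had 44.5.

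**Figure D3:**
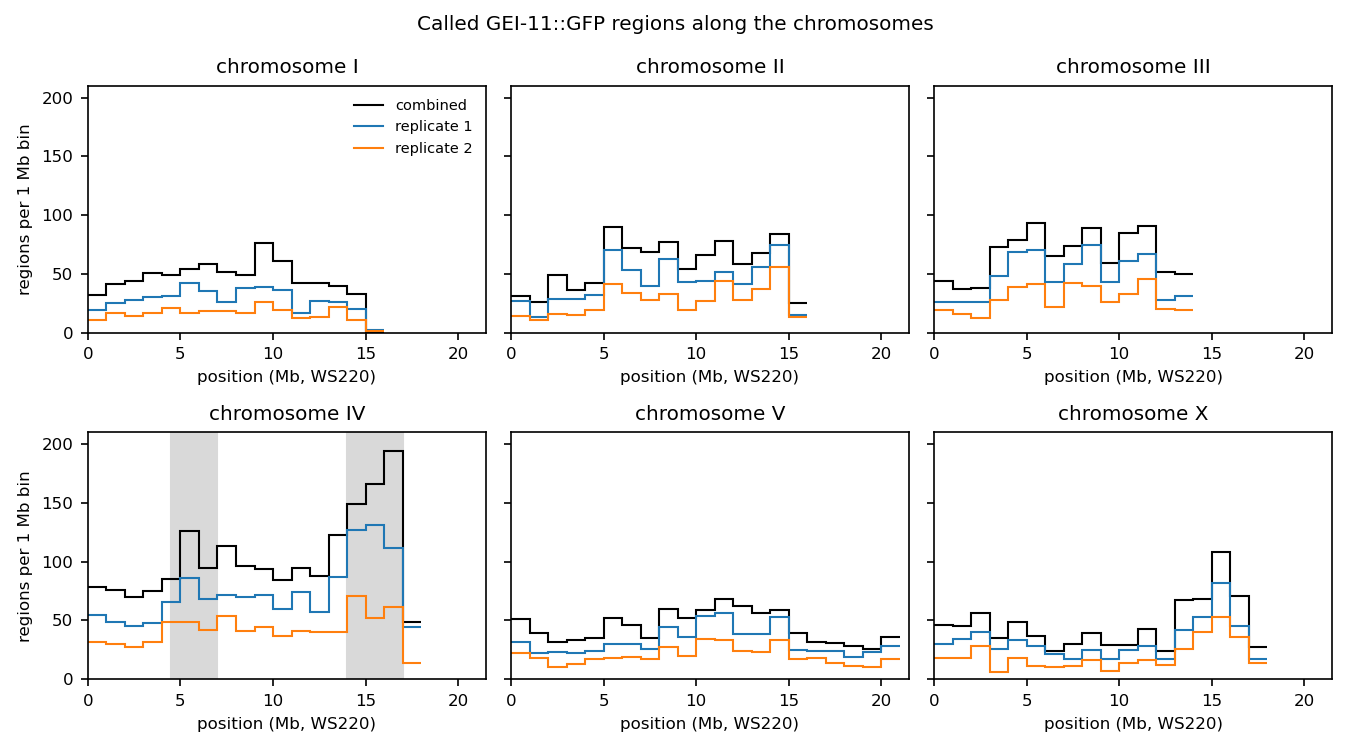
Number of called regions per 1 Mb bin (y axis) along each chromosome (x axis, Mb in WS220) for the combined, replicate 1 and replicate 2 lists, with the piRNA intervals of chromosome IV shaded. The last bin of each chromosome is partial. The fullest bin of the combined list is at 16 to 17 Mb of chromosome IV, with 194 regions.

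The third comparison asks whether the regions of chromosome IV gathered in the domains of piRNA genes. The right interval, 14 to 17 Mb, held 509 combined regions, or 170 per Mb (95% exact Poisson interval 155 to 185). The left interval, 4.5 to 7 Mb, held 257, or 103 per Mb (90.6 to 116). The rest of chromosome IV held 1090, or 91.0 per Mb (85.7 to 96.6). The right interval was thus 3.23 times as dense as the other chromosomes together, the left interval 1.96 times and the rest of chromosome IV 1.73 times. In replicate 1 these ratios were 3.35, 2.01 and 1.74, and in replicate 2 they were 2.72, 1.99 and 1.71. Without regions under 50 bp the right interval held 377 combined regions and the left interval 228. After merging of regions within 1000 bp the right interval held 393 and the left interval 213. Density ratios were not computed for these settings. Among combined regions found in both replicates the right interval was no denser than the left, with 38.3 per Mb (31.6 to 46.0) against 38.4 per Mb (31.1 to 46.9), and the ratios for the right interval, the left interval and the rest of chromosome IV were 1.99, 1.99 and 1.63. The strongest region in the intervals, at 14326597 to 14327588, had a −log10 q of 144 and was number 22 in the combined list. The next, in the left interval at 4880423 to 4881134, had a −log10 q of 118. Regions in the right interval were narrow, with a median width of 134 bp, while the left interval had a median of 293 bp, close to the 299.5 bp of the rest of chromosome IV. Narrow regions have less room to overlap regions of both replicates, and the intervals were not compared at like width.

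The concentration within chromosome IV did not pass the planned test. The intervals together held 766 of its 1856 combined regions, or 41.3%, against a mean of 31.6% and a highest value of 42.5% after circular shifts (two-sided permutation test, adjusted p = 0.16). The right interval alone held 27.4% against a mean of 17.2% (permutation p = 0.046, adjusted p = 0.14), and the left held 13.8% against 14.4% (adjusted p = 0.84 in the same permutation test). With the right interval widened by 0.5 Mb on each side it held 34.4% of the regions, and the permutation test passed (adjusted p = 0.018). From 13.5 to 17.2 Mb, the bounds usually given for this domain, it held 32.8% against a mean of 21.2% (permutation p = 0.022, adjusted p = 0.066). Among regions found in both replicates the intervals held 35.9% of the chromosome IV regions, against 31.5% after shifts (permutation test, adjusted p = 0.47). The shifts could be of any size, and a small shift leaves most of a broad dense stretch inside the same interval. Such shifts raise the p-value, so not passing this test does not argue against a concentration.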

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

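The alternative without regions under 50 bp, the one with full chromosome lengths, the merging of regions for the count of regions, the right interval from 13.5 to 17.2 Mb and the densities of chromosome IV areas in other lists or among regions found in both replicates were chosen after seeing the data. Of 98 alternatives to 17 values, 84 kept the side of the threshold and, except for the left interval, the direction. That interval rose above its shift mean in replicate 2 and among regions found in both. Untested values had to stay within the 95% exact interval of a share or density or within 1.5 times the main number of regions. The share of combined regions found in both replicates, 35.2%, moved to 31.3% with 50% reciprocal overlap, to 69.6% among the 3096 best scored regions and to 37.0% without regions under 50 bp. The best scored regions differ because weak regions were rarely found in both, and the cause was not tested for the other settings. The number of regions, 6192, fell to between 2617 and 4368 when a single replicate list was used. The right piRNA interval passed the permutation test only when widened by 0.5 Mb on each side, where it held 34.4% (adjusted p = 0.018). Over its other alternatives the adjusted p of this permutation test ran from 0.066, from 13.5 to 17.2 Mb, to 0.51, and that of both intervals together from 0.066 to 0.51. The overlap of the replicates ranged from 71.0% to 89.5% and the chromosome IV share from 26.9% to 30.3%, and both passed their tests in every alternative run. Chromosome II, at 0.98 times its share of length, was above its share in single replicate lists (1.02 to 1.09 times), among the 3096 best scored regions (1.04), without regions under 50 bp (1.01) and among regions found in both replicates, where alone it passed (1.12, exact binomial test, adjusted p = 0.023, against 0.053 to 0.77 in its other alternatives). Chromosome III lost its call among the 3096 best scored regions (1.08 times, exact binomial test, adjusted p = 0.091) and passed in its other alternatives (adjusted p from 7.4e-05 to 0.019, exact). The density ratio of the right interval, 3.23, moved to 2.72 in the replicate 2 list and to 1.99 among regions found in both, and that of the rest of chromosome IV from 1.73 to 1.63 among the latter. The cause was not tested. The planned tests on genes and on a motif were not run. No paired analysis was possible because the deposited lists hold no value for the input libraries by themselves. Of the combined regions, 30.7% were in neither replicate list, so a region missing from a replicate is not shown to be unbound there. How far depth limits these weak calls was not tested.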

Other observations

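The tests on region width by strength, on width by interval within chromosome IV, on the density of chromosome IV and on replicate support by interval were chosen after the result was seen. Of the width tests, only those of both intervals against all other regions, in the replicate 2 list and among isolated regions, were set before their result was seen.

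Chromosome X, which held fewer regions than its length gave, had a dense stretch near its right end. From 13 to 17 Mb it held 314 combined regions, or 78.5 per Mb, against 37.4 per Mb below 13 Mb. The bin from 15 to 16 Mb held 108 regions, more than any other full 1 Mb bin outside chromosome IV. The ratio of densities was 2.10 in the combined list, 2.12 in replicate 1 and 2.72 in replicate 2. Both replicates overlapped 130 of the 314 regions. The stretch was picked because it was dense, so no test was made. Elsewhere and on chromosome X together, 12 combined regions were wider than 3000 bp. The widest lay on chromosome V from 6224129 to 6230109, and the next on chromosome I from 5375085 to 5380272. All 12 were overlapped by at least 1 bp by regions of both replicates. Their full width was mostly not called there, since 1 region of replicate 1 and 2 of replicate 2 were wider than 3000 bp.

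Regions in the right piRNA interval were narrow, with a median width of 134 bp against 299.5 bp for the rest of chromosome IV and 355 bp for all regions outside the intervals, and 132 of the 509 were under 50 bp wide. The left interval, at 293 bp, did not pass against the rest of chromosome IV (permutation p = 0.66). Within classes of like strength, however, its median difference averaged -54.8 bp and passed (permutation p = 0.001). Against all regions outside the intervals its difference was -62 bp and also passed (permutation p = 0.0001). Weakness is argued against as the whole cause, since within 10 such classes the difference averaged -157.6 bp for the right interval against the rest of chromosome IV and -182.8 bp for both intervals against all others (permutation p = 0.001 for each, the smallest that 1000 resamples can give). Pooling of the replicates as the whole cause is argued against by the replicate 2 list, with -122 bp and -86 bp in the same order. Splitting of broad enrichment into several called pieces is argued against by regions with no called neighbour within 5000 bp, with -186 bp and -171 bp. Each of these differences had a permutation p of 0.0001, the smallest that 10000 resamples can give. Against the rest of chromosome IV, both intervals together gave -133 bp within classes, -57.5 bp in replicate 2 and -115.5 bp among isolated regions. The left interval alone gave -13.5 bp in replicate 2 (permutation p = 0.39) and 12.5 bp among isolated regions (permutation p = 0.69). The replicate 2 and isolated-region checks thus speak for the right interval only. Only 68 regions of the right interval and 139 of both intervals were so isolated. Broad enrichment called as a single short piece would also look isolated, so that case was not tested. The width tests treat regions as independent, which neighbouring regions are not. Trimming by the peak caller or poor mappability of short reads may still contribute, and no biological explanation was tested.

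Chromosome IV was dense also outside the piRNA intervals, at 91.0 regions per Mb. If the domains only reached beyond the intervals, the stretch from 8 to 13 Mb would look like other chromosomes, but it held 91.4 per Mb, above each of 60 overlapping windows of 5 Mb, set 1 Mb apart, on the other chromosomes, of which the highest held 80 (chromosome III, 4 to 9 Mb). The same order held in replicate 1, 66.6 against 63, in replicate 2, 40.6 against 38.4, and among regions found in both replicates, 33.8 against 32.6, so the margin over the densest window elsewhere was small. Weak calls alone do not account for it, since 16.3% of the 620 strongest regions (95% exact interval 13.5 to 19.4%) lay on chromosome IV outside the intervals, against 12.0% of the length. Scattered piRNA genes along the chromosome and uneven mappability may both play a part and were not tested, and no biological explanation was tested.

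The strongest region of each replicate list, on chromosome II from 5543219 to 5544605 in replicate 1, overlapped no combined region analysed here, and the nearest lay 20787 bp away. Of 2197 regions matched between the replicates, 1 other had no combined region, on chromosome I from 15060778 to 15060831. Why these had none was not tested, and statements about the combined regions hold only for those analysed here.

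Of the replicate 1 regions, 369 had no combined region. These were narrow, with a median of 79 bp against 337 bp for the rest of that list, and 29.8% of them lay in the piRNA intervals, against 11.13% of the rest. In replicate 2, 12 of the 19 such regions lay in the intervals, or 63.2% against 10.9%. Of the regions in the right interval, 22.6% were found in both replicates, against 37.4% in the left interval (Fisher's exact test, adjusted p = 5e-05) and 36.3% outside the intervals (Fisher's exact test, adjusted p = 8.7e-10). The left interval against regions outside did not pass (Fisher's exact test, adjusted p = 0.74). The rest of chromosome IV had 34.5% against 36.7% on the other chromosomes (Fisher's exact test, p = 0.24 adjusted over the 4 tests). Fisher's test treats neighbouring regions as independent, so these p-values are too small to the extent that regions cluster. Combined regions in the intervals together were not weaker than those outside, with a median −log10 q of 4.27 against 4.13. Narrow regions, as in the right interval, have less room to overlap, and support was not compared at like width.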
